A study of Mus musculus with 102 samples.

How the data were processed

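Chromatin immunoprecipitation with sequencing (ChIP-seq) was analysed from deposited processed tables of mouse embryonic stem (ES) cells. The labels describe 102 libraries in 49 groups. Of these, 45 came from 129/Ola ES cells, 28 from R1 ES cells that were wild type or carried catalytically inactive MLL3 and MLL4 (catalytic-dead line), 14 from MLL3/4 double-knockout cells and 15 from their floxed parental cells. Groups were taken from the sample titles and genotypes. Most replicates carry a number, but nothing in the labels says that they came from separate cultures.

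Per the submitters' processing notes the genome build was mm9. For 74 libraries the notes name Bowtie, Picard and MACS2 without versions, and for 28 libraries they name BWA 0.7.13-r1126, Picard 2.11.0, MACS2 2.1.0.20150731, deepTools 2.5.1 and deepTools 2.5.3. The role and order of these tools, and whether and how replicates were pooled, are not given in the sources used here.

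The authors deposited 3 peak tables, for H3K4me1, H3K4me2 and H3K4me3 in R1 cells, each with the position, a distal or proximal group, a class of change and a fold enrichment in wild-type and catalytic-dead cells. The file headers mark these values as FE, read here as a fold (ratio) enrichment. There is 1 value per line, while the labels give 2 libraries per mark and line, and which libraries entered a value is not stated. Neither the spread between libraries nor the depth is known, so no test between the lines was possible. What the enrichment is relative to, how peaks were called and how far a peak may lie from a promoter to be called proximal are not given in the sources used here. The deposited class of change was checked against the values: a peak was called decreased at a ratio of 0.5 or below and increased at a ratio of 2 or above, with 0 exceptions in each table. The word called refers to this rule of size and not to a test.

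The authors also deposited 3 region tables from 129/Ola cells, which give for each region the factors present with a log2 enrichment, 1 value per factor. Values below a log2 enrichment of 0.585, a fold of 1.5, are not listed, so a factor that is not listed at a region is below that limit or was not measured there. H3K4me1 and H3K4me3 carry no graded value in these tables and were used as presence. The tables hold 31 names, of which 20 were used: 17 factors, H3K27ac and the 2 H3K4 marks. The other 11 names matched no library of 129/Ola cells in the labels and were not used. The lists of active and poised enhancers are subsets of the regions with H3K4me1 and without H3K4me3. Each listed enhancer has at least 1 of 13 names, and the lists are separated at an H3K27ac log2 enrichment of 1, both checked in the tables. The share of regions with a factor is therefore raised in both lists by their selection.

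The score columns of the 3 peak tables were found to be out of step with the positions. Positions run through the chromosomes in text order (1, 10 to 19, 2 to 9, X, Y), while the values were laid out in number order. On chromosome 1, where both orders coincide, Spearman's rho of peak width with wild-type fold enrichment was 0.215 for H3K4me1, 0.661 for H3K4me2 and 0.674 for H3K4me3. On chromosomes 2 to 19, which hold 92.4%, 92.0% and 91.8% of the peaks, the mean rho in the deposited layout was 0.00253, 0.00546 and -0.00380. With the values put back in number order it was 0.253, 0.675 and 0.687, against at most 0.0332, 0.0780 and 0.0688 in 200 random chromosome orders. The restored order was used for every result that ties a value to a position. This choice was made after the data were examined, and results in the deposited layout are given in the closing section. If the restored order is right, the deposited layout pairs most peaks with values of other peaks. That draws distal and proximal medians towards the table median, and differences and rho towards 0. Results in that layout are therefore no independent check. Counts over a whole table do not depend on the order. The distal and proximal groups follow the positions: 96.2% of overlapping H3K4me2 and H3K4me3 peaks, 91.6% of H3K4me1 and H3K4me2 peaks and 89.4% of H3K4me1 and H3K4me3 peaks had the same group.

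From these tables the log2 ratio of catalytic-dead over wild-type fold enrichment was computed without a pseudocount. A value of 0, found at 2 H3K4me2 peaks, was replaced by the lowest positive value divided by 2. Shares and medians have 95% intervals from 500 resamples of 5 Mb genome blocks, which cover variation along the genome and not the error between libraries. Peaks of different marks, and peaks and regions, were matched at 1 bp of overlap or more with bedtools 2.31.1. Fisher's exact test treats peaks as independent, which they are not. Differences in the share of regions with a factor were tested across the 17 factors with a two-sided sign-flip permutation test of 100000 resamples, whose smallest possible p is 1e-05. Factors share regions and input libraries, so this test measures how general a difference was over factors. Correlations are across peaks or regions, which are not independent replicates. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

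The tests fixed before the data were examined assumed values per library. As the tables hold 1 value per group, these tests were replaced by counts, shares, medians and the permutation over factors. The deposited calls were used unfiltered and without a pseudocount, where a filter on the lowest 25% of mean values had been planned, and the filtered counts are given beside them. Comparisons of the double knockout with the floxed parental cells, and of H3K27ac, BRG1 and DPF2 in the catalytic-dead line, were not analysed here. Peaks were named by a rule fixed before the data were examined: per mark the 5 largest falls and rises among peaks whose mean of both lines was above the median. The peaks with the highest and lowest wild-type values, also planned, are left out of the text because picking by 1 line bears on the direction of their ratio. Peaks are given by mm9 position as in the tables. Starts of the region lists were converted to count from 1, and the peak tables do not state from where they count. The gene table at hand belongs to another assembly than mm9, so no gene was assigned to a position and the gene lists fixed in advance were not used. Factors were described by complexes fixed in advance.

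The restoring of the score order, the shares and their intervals, the sign-flip test, the width standardisation and the overlaps were tested on simulated data, the other steps were not. In simulated tables of 82053 H3K4me1, 53501 H3K4me2 and 34553 H3K4me3 peaks for the comparison of the lines, 100% of values were put back in place, and 97.0%, 94.5% and 96.0% of intervals held the true distal share. The simulated values were moved by the same order that was then undone, so this checks the code and not which order is right. For the comparison across 17 factors, the sign-flip test gave a p under 0.05 in 3.00% of draws with no effect. Simulated calls and factors were drawn independently, so dependence along the genome or between factors was not covered. Alternatives tried were other normalizations, pseudocounts, filters on low values, overlaps and region sets, the layout of the scores and single chromosomes.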

Results

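Binding of chromatin proteins and histone H3 lysine 4 (H3K4) methylation were profiled by ChIP-seq in mouse ES cells, to ask which proteins share sites with H3K4me1 and which of them depend on it. MLL3 and MLL4 are the main methyltransferases for H3K4me1 at enhancers. R1 ES cells with wild-type MLL3/4 were compared with R1 cells with catalytically inactive MLL3/4 (catalytic-dead cells). For this the labels give 12 libraries, 2 per mark and line for H3K4me1, H3K4me2 and H3K4me3. In 129/Ola ES cells, 17 factors were measured, 14 of them in 2 libraries, 2 in 3 libraries and SSRP1 in 1 library. The deposited tables give 1 value per mark or factor and no counts, so the depth is unknown, there is no replicate check, and the intervals given are from resampling genome blocks. The tables of the R1 lines hold 82053 H3K4me1, 53501 H3K4me2 and 34553 H3K4me3 peaks, and their values were first put back in step with the positions.

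**Figure D1:**
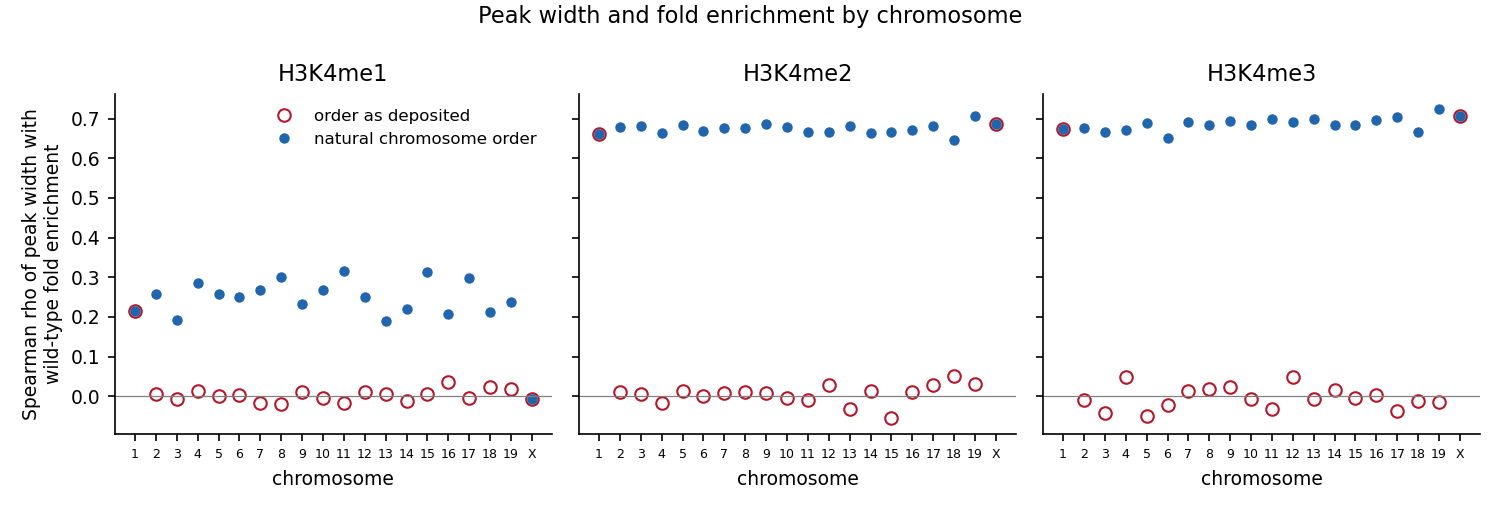
Spearman's rho of peak width with wild-type fold enrichment (y axis) on each chromosome (x axis) for the 3 marks in R1 cells, with values as deposited (open circles) and in restored order (points). On chromosomes 2 to 19 the mean rho for H3K4me3 was -0.00380 as deposited and 0.687 restored, against 0.674 on chromosome 1, while for H3K4me1 it was 0.00253, 0.253 and 0.215.

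The first comparison asked where H3K4me1 changed when MLL3/4 lost their catalytic activity. At distal peaks, which lie away from promoters, the median H3K4me1 fold enrichment was 3.04 in wild-type and 2.04 in catalytic-dead cells, a median log2 ratio of -0.65 (-0.68 to -0.62, 57381 peaks). At proximal peaks it was 2.64 and 4.38, a median log2 ratio of 0.84 (0.82 to 0.85, 24672 peaks). Of the distal peaks 37.7% (36.8 to 38.8) were at least 2-fold lower and 5.66% at least 2-fold higher in catalytic-dead cells. Of the proximal peaks 6.79% were lower and 37.3% (36.1 to 38.5) higher. The median was below 0 at distal peaks and above 0 at proximal peaks on each of the 19 autosomes, from -0.80 to -0.55 and from 0.70 to 0.98. On the X chromosome the medians were -0.51 at distal and 1.12 at proximal peaks.

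Over the whole table, 23336 H3K4me1 peaks were called decreased and 12443 increased. The odds of a decrease were 8.33 times higher at distal than at proximal peaks and those of an increase 0.101 times as high, in that direction on 20 of 20 chromosomes. The share of decreases was 31.0 points higher at distal peaks, but 3.81 among peaks with a mean above the median and 2.05 in the deposited layout, where that of increases went from -31.6 to -3.34. Decreases made up 65.2% of the calls, 50.4% after median centring, which shifts the log2 ratios by 0.21, and 45.3% after quantile normalization. Both settings move the lines towards balance by construction and decide nothing about it, and the tables do not fix the scale between the lines. Without the lowest 25% of peaks by the mean of both lines, the filter planned before the data were examined, 6627 peaks were decreased and 12073 increased, a share of decreases of 35.4%. Among peaks whose mean of both lines was above the median the distal median was 0.19, and among peaks above the wild-type median the distal and proximal medians were -0.92 and 0.18. Each of these filters uses values that enter the ratio, and the mean depends most on the catalytic-dead values, which spread more (quartiles 1.44 to 4.13 against 2.56 to 3.32), so none is independent of the change. In the deposited layout of the values the proximal median was -0.10. If that layout is out of step, it draws medians towards that of the whole table and differences in share towards 0.

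Among peaks with a mean of both lines above the median, the largest falls in H3K4me1 were at distal peaks. The fold enrichment was 5.27 in wild-type and 0.468 in catalytic-dead cells at chromosome 7, 110547071 to 110547739, a log2 ratio of -3.49. It was 5.39 and 0.771 at chromosome 7, 120182290 to 120184013, and 4.93 and 0.745 at chromosome 8, 122151132 to 122152865. The 5 largest falls had log2 ratios from -3.49 to -2.54. Of the 5 largest rises 3 were proximal, among them chromosome 2, 122463098 to 122464199, with a fold enrichment of 0.976 in wild-type and 4.94 in catalytic-dead cells, and 2 were distal, among them chromosome X, 72918266 to 72919236, with 1.03 and 5.22.

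H3K4me2 was also lower at distal peaks of catalytic-dead cells and slightly higher at proximal peaks. The median fold enrichment at distal peaks was 4.11 in wild-type and 3.13 in catalytic-dead cells, a median log2 ratio of -0.46 (-0.48 to -0.45, 35286 peaks), and 31.8% were called decreased against 2.05% increased. At proximal peaks it was 8.47 and 9.87, a median log2 ratio of 0.18 (0.17 to 0.19, 18215 peaks), with 5.91% decreased and 1.64% increased. Among peaks with a mean of both lines above the median, the largest fall was at a distal peak on chromosome 14, 54181981 to 54183372, from a fold enrichment of 9.11 to 0.850. Under this limit the largest rise was at a proximal peak on chromosome 9, 121845683 to 121848158, from 1.68 to 9.48.

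In all, 12302 H3K4me2 peaks were called decreased and 1023 increased, and the odds of a decrease were 7.42 times higher at distal peaks. The share of decreases was 25.9 points higher at distal peaks, but 2.85 among peaks with a mean above the median and 2.77 in the deposited layout. Increases were also more frequent at distal peaks, with an odds ratio of 1.26 (Fisher's exact test, two-sided, p = 0.000967, peaks taken as independent), but only on 14 of 20 chromosomes, and the difference in share, 0.41 percentage points, was -1.25 on chromosomes 1 and X and -0.256 in the deposited layout. Decreases made up 92.3% of the calls, 87.8% after median centring (11035 decreased, 1527 increased) and 50.7% after quantile normalization, with 4353 decreased and 4238 increased peaks and medians of -0.08 at distal and 0.03 at proximal peaks. Without the lowest 25% of peaks 3083 were decreased and 800 increased. Among peaks with a mean above the median the distal log2 ratio was 0.03, among those above the wild-type median -0.21, and in the deposited layout the proximal one was -0.07.

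H3K4me3 differed little between the lines. The median log2 ratio was -0.07 (-0.08 to -0.05) at 18030 distal peaks and -0.01 (-0.02 to -0.01) at 16523 proximal peaks, and 92.4% of all peaks were within 2-fold. Decreases were called at 7.17% of distal and 1.54% of proximal peaks and increases at 5.04% and 1.09%. These differences of 5.62 and 3.95 points were 0.206 and 0.310 in the deposited layout. Among peaks with a mean of both lines above the median they were 0.718 and 0.475. Under the same limit on the mean, the largest rise lay at a proximal peak on chromosome 9, 121846453 to 121848017, with a fold enrichment of 2.27 in wild-type and 13.4 in catalytic-dead cells, within the H3K4me2 peak with the largest rise. The largest fall under it, from 10.7 to 2.49, was at a distal peak on chromosome 9, 100869075 to 100870188.

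The 1547 decreased and 1089 increased H3K4me3 peaks made a share of decreases of 58.7%, which was 54.6% after median centring (1451 decreased, 1205 increased), 58.8% and 58.7% with pseudocounts of 0.1 and 1, 40.0% after quantile normalization and 42.4%, with 302 decreased and 411 increased, without the lowest 25% of peaks. The proximal median was 0.02 both after median centring and on chromosomes 1 and X, so its sign was not resolved.

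**Figure D2:**
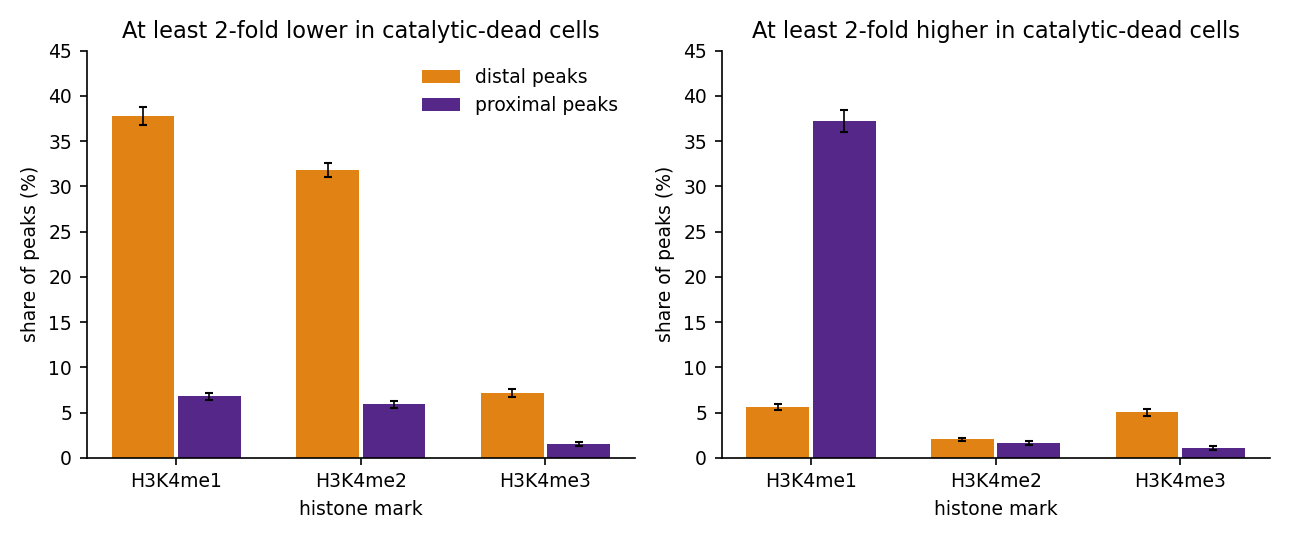
Share of distal and proximal peaks (y axis, percent) at least 2-fold lower (left) or higher (right) in catalytic-dead than in wild-type R1 cells for each mark (x axis), with 95% intervals from genome blocks as error bars. Decreases were most frequent at distal H3K4me1 (37.7%) and H3K4me2 peaks (31.8%) and increases at proximal H3K4me1 peaks (37.3%). In the deposited layout of values the proximal H3K4me1 median log2 ratio was -0.10. A layout out of step draws each group towards the table median, which was -0.21.

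Where peaks of different marks overlapped, lower H3K4me1 in catalytic-dead cells went with lower H3K4me2. Of 7275 overlapping pairs with decreased H3K4me1, 91.8% (Wilson interval 91.1 to 92.4, counting error only) had decreased H3K4me2. Of 1081 pairs of decreased H3K4me1 with an H3K4me3 peak, 34.5% had decreased H3K4me3. Where H3K4me1 was unchanged, 14.6% of pairs had decreased H3K4me2 and 2.82% decreased H3K4me3. Where H3K4me1 was called increased, 96.4% of 12002 H3K4me2 partners and 98.5% of 11556 H3K4me3 partners were unchanged. With unchanged H3K4me1 it was 84.8% and 94.4%. Increased H3K4me2 was found in 3.57% of pairs with increased and 0.579% with unchanged H3K4me1, and increased H3K4me3 in 1.38% and 2.78%. Across overlapping peaks Spearman's rho of the log2 ratios was 0.83 for H3K4me1 with H3K4me2, 0.48 for H3K4me2 with H3K4me3 and 0.16 for H3K4me1 with H3K4me3.

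Most distal peaks called decreased in H3K4me1 carried no peak of the other marks: 28.9% overlapped an H3K4me2 peak and 4.17% an H3K4me3 peak, against 98.9% and 97.9% of the proximal peaks called increased. It was 29% and 7.34% at proximal peaks called decreased and 84.9% and 73.8% at distal peaks called increased, so the low overlap was not a feature of distal peaks alone. The relation of H3K4me1 to H3K4me3 turned between the lines. Across overlapping peaks rho of their fold enrichments was -0.40 in wild-type and 0.57 in catalytic-dead cells, and at proximal peaks alone -0.30 and 0.31. The turn was not particular to H3K4me3. For H3K4me1 with H3K4me2, rho was -0.27 in wild-type and 0.83 in catalytic-dead cells. At distal peaks alone it was -0.025 and 0.84, and at proximal peaks alone -0.11 and 0.56. Between the lines, rho of the fold enrichment was -0.35 for H3K4me1, 0.78 for H3K4me2 and 0.88 for H3K4me3. These correlations are across peaks, and no test between libraries was possible. The labels give 1 set of input libraries per line for all marks, and ratios with a shared input would correlate without a change, a part that was not measured. In the deposited layout the rho values of the changes were 0.09 for H3K4me1 with H3K4me2, 0.04 for H3K4me2 with H3K4me3 and 0.02 for H3K4me1 with H3K4me3.

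The changes were next set against the regions defined in 129/Ola cells, a different ES line. H3K4me1 was lower in catalytic-dead cells at peaks on active enhancers (median log2 ratio -0.73, -0.76 to -0.70, 10445 peaks) and on poised enhancers (-0.66, -0.70 to -0.63, 12235 peaks). It was higher at peaks on regions with both H3K4me1 and H3K4me3 (0.58, 0.55 to 0.60) and at peaks on regions with H3K4me3 only (1.06, 1.05 to 1.07). Of the latter peaks 56.5% were called increased. Their regions lack H3K4me1 in 129/Ola cells by definition, and their median wild-type fold enrichment, 2.37, was the lowest of these sets. How peaks were called is not known, so a peak list that favours low wild-type values may add to this rise. H3K4me2 had medians of -0.96 (-1.01 to -0.94) at active and -0.57 (-0.60 to -0.54) at poised enhancers, 0.11 at regions with both marks and 0.23 at H3K4me3-only regions. H3K4me3 medians at active and poised enhancers were -0.06 and 0.02. The 24972 H3K4me1 peaks on no listed region had a median of -0.82. Among peaks with a mean above the median the active and poised values for H3K4me1 were -0.26 and 0.09, and in the deposited layout that at regions with both marks was -0.15. In that layout the value at H3K4me3-only regions was also far lower, as given in the closing section.

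The second set of comparisons asked which chromatin proteins share sites with H3K4me1 in 129/Ola cells. The regions comprised 41819 with H3K4me1 only, 18425 with both marks and 7453 with H3K4me3 only. H3K4me1-only regions carried fewer factors, 3.27 of 17 on average, than regions with both marks (9.22) or H3K4me3 only (7.81), and H3K27ac, a mark of active elements, was listed at 46.4%, 88.3% and 89.9%. SRSF2, a splicing factor, was the factor most often listed at H3K4me1-only regions (39.5%), followed by the splicing factor SRSF1 (26.7%), the ISWI ATPase SNF2H (25.5%) and the cohesin subunit SMC3 (24.9%). WSTF, a partner of SNF2H, was listed least often (8.45%), followed by the BAF subunit BAF155 (10.1%).

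All 17 factors were listed less often at H3K4me1-only than at H3K4me3-only regions, by 26.7 percentage points on average (mean difference -26.7 ± 17.3, SD over factors; sign-flip permutation test over factors, p = 3e-05). The largest difference was that of the RuvBL ATPase RUVBL2, at 16.9% against 81.7%, followed by SAP18 at 21.5% against 73.7% and RUVBL1 at 14.6% against 61.0%. The 3 Mediator subunits were at 17.2% against 42.3% on average and the ISWI proteins at 16.7% against 28.8%. The smallest differences were those of WSTF (-5.09 points), BAZ1A (-5.64) and the splicing-related PHD protein PHF5A (-5.66). With shares standardised to region width they were -7.83, -12.4 and -11.1 points, with 17 of 17 factors lower and a mean of -25.9. Among regions with a mean factor value above the median the mean difference was -17.1 points and 15 of 17 factors were lower, a filter that selects by the factors compared.

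Regions with both marks had 14 of 17 factors more often than H3K4me3-only regions, by 8.29 points on average (p = 0.00773, permutation over factors). The largest differences were in SSRP1, a subunit of the histone chaperone FACT, at 64.9% against 33.9%, in PHRF1, a PHD-finger protein, at 66.9% against 37.9%, and in the Mediator subunit SUR2 at 59.6% against 38.7%. RUVBL2 (by -11.7 points), RUVBL1 (57.2% against 61.0%) and WSTF (10.2% against 13.5%) were less frequent, but with shares standardised to region width the differences of RUVBL2 and RUVBL1 were -3.49 and 2.94 points and 15 of 17 factors were higher. This mean difference was 1.2 points among regions with a mean factor value above the median (p = 0.596, permutation over factors), with 7 of 17 factors higher, but this filter selects regions by the factors that are then compared.

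**Figure D3:**
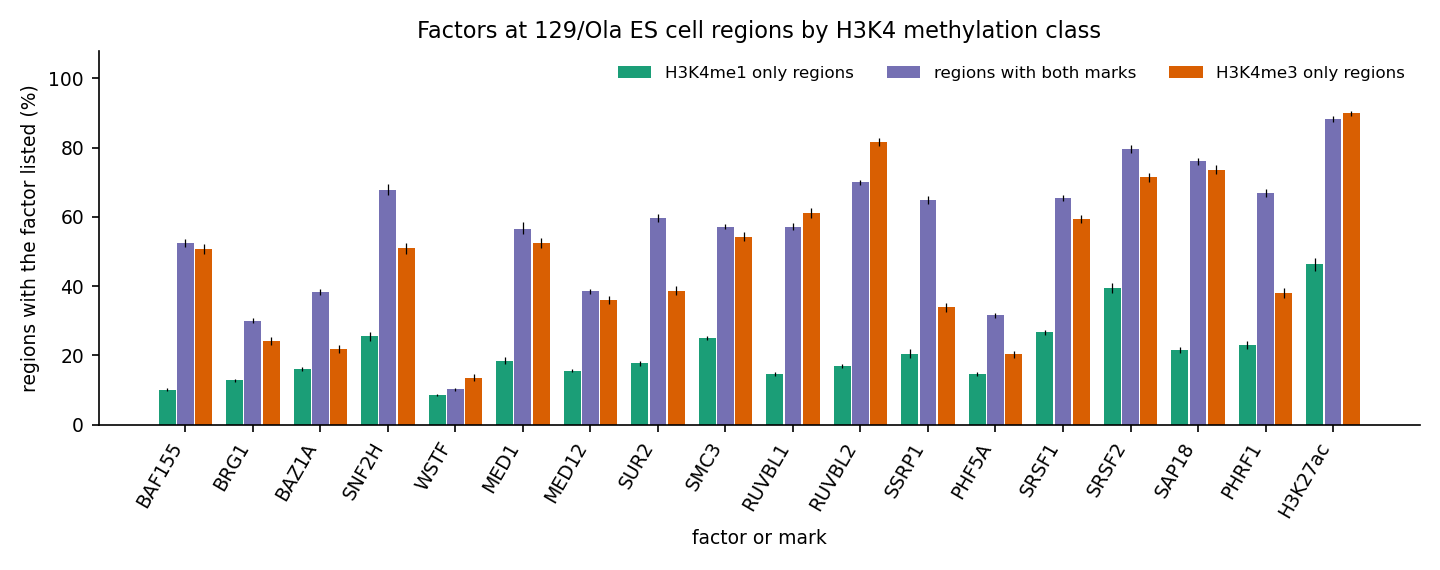
Share of 129/Ola regions at which each factor was listed (y axis, percent), for 41819 H3K4me1-only, 18425 both-mark and 7453 H3K4me3-only regions, with 95% intervals from genome blocks as error bars. Each of the 17 factors was least frequent at H3K4me1-only regions, and SSRP1 and PHRF1 stood highest at regions with both marks relative to H3K4me3 only, at 64.9% against 33.9% and 66.9% against 37.9%.

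Active enhancers (12492 regions) had more factors than poised ones (19567 regions), 5.41 against 3.45 on average. SSRP1 was listed at 38.4% of active and 17.2% of poised enhancers, SAP18 at 38.1% and 19.6%, and PHRF1 at 41.0% and 22.9%. The BAF subunits differed less in BRG1 (20.2% and 14.5%) than in BAF155 (19.8% and 8.02%). SMC3 was listed at 37.1% and 29.6%. WSTF went the other way, at 9.63% and 11.9%. The difference was above 0 for 16 of 17 factors, with a mean of 11.6 points ± 6.02 (SD over factors; sign-flip permutation, p = 3e-05). With shares standardised to region width the difference of WSTF was 0.0855 points and 17 of 17 factors were higher. At H3K4me1-only regions outside both lists BRG1, WSTF and SMC3 were listed at 0%, but BAF155 at 1.82%, SSRP1 at 4.01% and SAP18 at 4.06%. Selection of the lists thus bears unequally on the factors, and contrasts between factors can partly follow from it. Over all H3K4me1-only regions with and without listed H3K27ac, BRG1 was at 16.8% and 9.41%, BAF155 at 15.7% and 5.26%, and WSTF at 7.98% and 8.86%. This split lies at the listing limit and not at the log2 value of 1, so it does not check the lists. Of the 9760 H3K4me1-only regions outside both lists, 13.5% had an H3K27ac log2 value of 1 or more. Leaving these regions out raises the WSTF share mostly on the poised side, so the direction of WSTF was not resolved.

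The active enhancer with the highest H3K27ac log2 enrichment, 3.68, lay at chromosome 16, 93815855 to 93817176, and carried 6 of the factors. The next, also at 3.68, lay at chromosome 13, 37528539 to 37529113, with 10. The poised enhancer with the lowest listed H3K27ac value, 0.59, lay at chromosome 3, 10286660 to 10286940, with 6 factors.

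**Figure D4:**
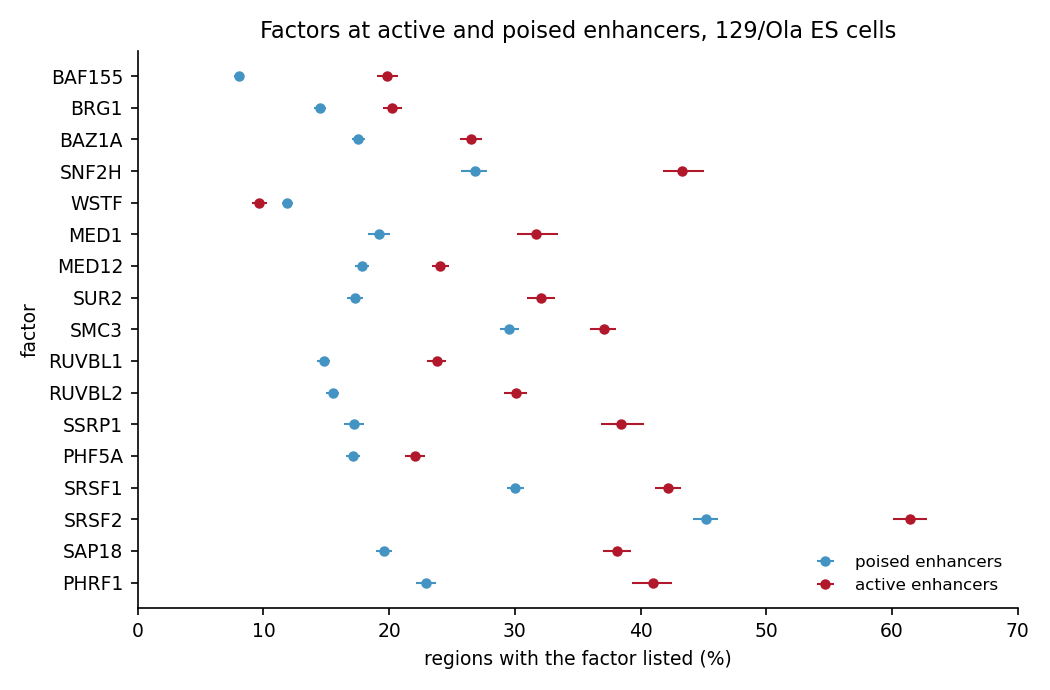
Share of active (red) and poised (blue) enhancers of 129/Ola cells at which each of 17 factors (y axis) was listed (x axis, percent), with 95% intervals from genome blocks as error bars. The red points lie to the right for 16 of 17 factors, by 21.2 points for SSRP1, and to the left for WSTF, by -2.28 points, a difference that was 0.0855 points when standardised to region width. Selection of the lists also bears on the WSTF difference.

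Factor values were weakly correlated with H3K27ac. Across H3K4me1-only regions, Spearman's rho of a factor's value with that of H3K27ac, with unlisted values at 0, was 0.189 on average over 17 factors, from -0.00443 for WSTF to 0.294 for SSRP1. Within active and within poised enhancers the mean rho was 0.0449 and 0.0583, and 0.0840 over regions where both values were listed. Both lists are cut at an H3K27ac log2 value of 1 and select by factor names. This narrows the range of values, so the lower rho within them decides nothing about a graded relation. H3K27ac was listed at 19.7% of regions with no factor, 39.4% with 1 to 3, 62.9% with 4 to 7, 79.8% with 8 to 12 and 87.7% with 13 to 17 factors (8595, 16971, 11635, 4357 and 261 regions). The correlation with H3K4me1 itself was not analysed here, as its value is not graded in the tables.

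Pairs of factors differed in how often they were listed together. At H3K4me1-only regions the mean phi coefficient was 0.159 (0.0342 to 0.220) over 14 pairs within a complex or among the splicing-related proteins, which are no single complex, and 0.161 over the other 122 pairs. The pair with the highest phi among factors was SSRP1 with PHRF1 (0.295), listed together at 4057 regions. Pairs with WSTF had a mean phi of 0.0293. The difference between the 2 kinds of pairs was not tested.

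The H3K4me1 difference between the lines was then compared between distal peaks with and without each factor, at 26253 distal H3K4me1 peaks on H3K4me1-only regions. Peaks with SMC3 had a smaller difference between the lines, a median log2 ratio of -0.55 against -0.85 without it (difference 0.30, 0.27 to 0.33), and 30.3% against 43.5% were called decreased. Peaks with BAF155 had a larger one, at -0.86 against -0.76 (difference -0.10, -0.14 to -0.06), and the differences for PHF5A and RUVBL2 were 0.11 and 0.08. For the other factors the difference lay between -0.06 and 0.05. Over the 17 factors there was no general direction: 11 were above 0 and 6 below (p = 0.212, permutation over factors), and binding was measured in another ES line than the change.

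The share of regions with some factors differed by chromosome. On chromosome 11, MED1, a Mediator subunit, was listed at 43.0% of H3K4me1-only regions, against a median of 16.1% over the other 18 autosomes. SNF2H was listed at 52.1% against 23.2% and SRSF2 at 64.8% against 37.2%, while BRG1 was at 13.4% against 12.5%. In this class every factor except BRG1, BAZ1A, SMC3 and SSRP1 was above the highest other autosome, for example MED12 (21.8% against 16.9%) and PHRF1 (33.1% against 27.8%). At regions with both marks 3 factors were instead below the lowest other autosome: BRG1 (25.3% against 28.6%), BAZ1A (30.5% against 35.7%) and SMC3 (52.7% against 53.7%). So were BRG1 (16.4% against 20%), BAZ1A (15.4% against 16.6%) and SUR2 (30.9% against 33.3%) at H3K4me3-only regions, while SUR2 was above the highest other autosome in the other 2 classes. Of the 17 factors, 4 were above the highest other autosome in each of the 3 region classes (MED1, SNF2H, SRSF2 and BAF155) and 3 in none. These factors were singled out after their values were seen, and without chromosome 11 the mean differences between region classes were -27.0, 8.06 and 11.4 points.

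**Figure D5:**
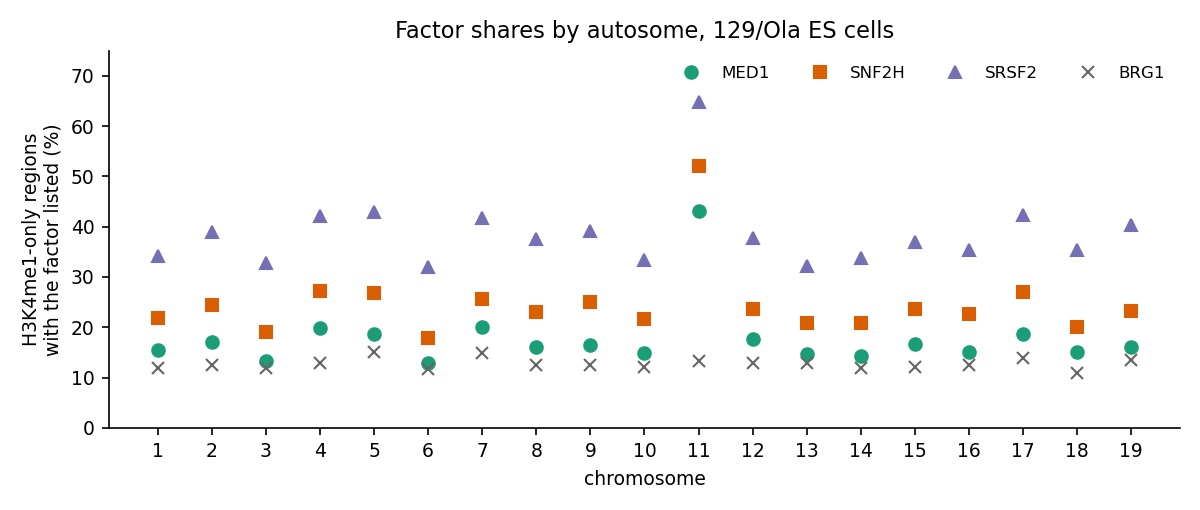
Share of H3K4me1-only regions of 129/Ola cells at which 4 factors were listed (y axis, percent) on each autosome (x axis). MED1, SNF2H and SRSF2 stand at 43.0%, 52.1% and 64.8% on chromosome 11, while BRG1 stands at 13.4% there.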

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

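Tests chosen only after the data were seen were median centring, both pseudocounts, quantile normalization of the medians, the deposited layout, chromosomes 1 and X only, the filter on wild-type values, a log2 value of 1 or more, standardised widths, leaving out chromosome 11, regions with both values listed and the split of all H3K4me1-only regions by H3K27ac. Of 192 alternatives for 29 results, 82 stayed within the main interval, the factor of 1.5 or the side of the threshold, 99 moved without a change of sign, 1 lost the threshold and 10 changed sign. Among these 10, 4 were in the deposited layout. The difference of H3K4me1-only from H3K4me3-only regions and that of active from poised enhancers kept their direction and side of the p threshold under each alternative run. This rule sets no limit on how far their size moved. Depth is unknown, so a peak or factor that is absent cannot be told from one missed at low depth. No paired analysis was possible because each line has 1 value per mark. For the same reason leaving out replicates, the replicate block, input subtraction and other test tools were not run, nor were larger or smaller pseudocounts for the factor shares. The double-knockout contrasts, the H3K27ac, BRG1 and DPF2 contrasts of the catalytic-dead line and the relation of factor change to H3K4me1 change were not analysed here. Except where stated, the cause of a move was not tested.

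With quantile normalization, 15381 H3K4me1, 4353 H3K4me2 and 1016 H3K4me3 peaks were decreased and 4238 H3K4me2 peaks increased. Median log2 ratios at distal and proximal peaks were -0.46 and 0.94 for H3K4me1, -0.081 and 0.031 for H3K4me2 and -0.050 at distal peaks for H3K4me3, and those of H3K4me1 at active, poised, both-mark and H3K4me3-only regions were -0.65, -0.49, 0.45 and 1.35. With median centring, 18813 H3K4me1 peaks were increased, the distal and proximal medians were -0.44 and 1.04 for H3K4me1, -0.34 and 0.31 for H3K4me2 and -0.035 and 0.019 for H3K4me3, the last with its sign changed, and the 4 region medians were -0.52, -0.45, 0.79 and 1.27. Centring adds a constant, which accounts for these moves.

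With a pseudocount of 1, which shrinks ratios by construction, 13051 H3K4me1 peaks were decreased and 4212 increased, 431 H3K4me2 peaks increased, and 682 H3K4me3 peaks decreased and 480 increased. The distal and proximal medians were -0.46 and 0.64 for H3K4me1 and -0.37 and 0.16 for H3K4me2, and the region medians -0.52, -0.47, 0.45 and 0.81. With 0.1, the H3K4me1 medians were 0.81 at proximal peaks, -0.70 at active and 1.03 at H3K4me3-only regions. With the mean in place of the median they were 0.59 at proximal peaks, -0.76 at active, 0.43 at both-mark and 1.01 at H3K4me3-only regions, and the H3K4me2 means were -0.70 at distal and 0.061 at proximal peaks. With an overlap of 50% of the smaller peak the H3K4me1 median at H3K4me3-only regions was 1.04.

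Without the lowest 25% of peaks by mean value, 6627 H3K4me1, 3083 H3K4me2 and 302 H3K4me3 peaks were decreased and 411 H3K4me3 peaks increased. Among peaks with a mean above the median, the distal medians of H3K4me1 and H3K4me2 changed sign to 0.19 and 0.031 and that of H3K4me1 at poised enhancers to 0.088. The proximal medians were 0.92 and 0.22, those of H3K4me3 -0.012 at distal and -0.0037 at proximal peaks, and those of H3K4me1 at active and both-mark regions -0.26 and 0.67. The share decreased at distal minus proximal peaks was 3.81, 2.85 and 0.718 points for the 3 marks in turn, that increased 0.475 for H3K4me3, and rho of the changes 0.616 for H3K4me1 with H3K4me2 and 0.671 for H3K4me2 with H3K4me3. The mean of both lines contains the catalytic-dead values, which for H3K4me1 spread more than those of wild type (quartiles 1.44 to 4.13 against 2.56 to 3.32), so these filters are not independent of the change. Among peaks above the wild-type median, where the denominator of the ratio is selected, distal and proximal medians were -0.92 and 0.18 for H3K4me1, -0.21 and 0.21 for H3K4me2 and -0.11 at distal peaks for H3K4me3.

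In the deposited layout, distal and proximal medians were -0.25 and -0.10 for H3K4me1, -0.16 and -0.073 for H3K4me2 and -0.036 and -0.029 for H3K4me3, so the proximal H3K4me1 and H3K4me2 medians changed sign. The whole-table medians were -0.21, -0.13 and -0.033 for the 3 marks in turn. If that layout is out of step, medians near these, and differences and rho near 0, follow by construction. The H3K4me1 medians at active, poised, both-mark and H3K4me3-only regions were -0.26, -0.25, -0.15 and 0.011, the both-mark one with its sign changed. Distal minus proximal shares were 2.05, 2.77 and 0.206 points for decreases and -3.34, -0.256 and 0.310 for increases, with the H3K4me2 increase changed in sign, and rho of the changes was 0.0910 for H3K4me1 with H3K4me2, 0.0191 for H3K4me1 with H3K4me3 and 0.0367 for H3K4me2 with H3K4me3. On chromosomes 1 and X, where the layout needs no restoring, distal and proximal medians were -0.77 and 0.97 for H3K4me1, -0.51 and 0.28 for H3K4me2 and, at proximal peaks with its sign changed, 0.015 for H3K4me3. Region medians were -0.79, -0.83, 0.69 and 1.12, the shares differed by 38.2 (H3K4me1) and 30.7 (H3K4me2) points for decreases and by -40.6 (H3K4me1), -1.25 (H3K4me2, sign changed) and 3.46 (H3K4me3) for increases, and rho of H3K4me1 with H3K4me3 changes was 0.139.

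Among regions with a mean factor value above the median, both-mark regions exceeded H3K4me3-only regions by 1.2 points (p = 0.596, permutation over 17 factors), a filter that selects by the factors compared, and p over the other alternatives of this result ran from 0.00018 to 0.0171. The mean correlation with H3K27ac was 0.182 as Pearson's r, 0.0449 within active and 0.0583 within poised enhancers, and 0.0840 where both values were listed. Both enhancer lists are cut on H3K27ac itself, which narrows its range.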

Other observations

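All tests of explanations were chosen after the result they measure was seen, except the test of proximal peaks with high wild-type values and the test of chromosome 11 regions without H3K27ac.

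The X chromosome held few regions with H3K4me1 in 129/Ola cells: 86 of 41819 H3K4me1-only regions and 156 of 18425 regions with both marks lay on it, against 401 of 7453 with H3K4me3 only. In the R1 lines 524 distal and 664 proximal H3K4me1 peaks lay on the X chromosome. There, 61.9% of proximal and 16.8% of distal H3K4me1 peaks were called increased in catalytic-dead cells, above the highest autosome at 48.6% and 8.74%, and the share of proximal H3K4me2 peaks called increased was 5.48%, against at most 3.78% on an autosome. Decreases were also more frequent at distal H3K4me2 peaks of the X chromosome, at 39.8% against at most 34.5% on an autosome. At H3K4me1-only regions WSTF was the only one of 17 factors listed with H3K27ac less often than independent lists would give, with 1550 regions shared against 1641.

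A first pattern was that fold enrichment had no relation to peak width on chromosomes 2 to 19 in the deposited layout of the 3 peak tables. A real absence of the relation is argued against by the restored order, in which rho of H3K4me2 with H3K4me3 wild-type fold enrichment at overlapping peaks was at least 0.804 on each of these chromosomes. A candidate explanation is that values were written in number order beside positions in text order: with that order undone, the mean width rho lay within 0.0378 of chromosome 1 for each mark. For H3K4me1 on the X chromosome, where both orders coincide, the width rho was -0.00637, so that relation does not hold on every chromosome. No biological explanation was tested.

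A second pattern was higher H3K4me1 at proximal peaks of catalytic-dead cells. One scale factor for all peaks would keep ranks, but rho of H3K4me1 with H3K4me3 across proximal peaks differed by 0.607 between the lines. A scale factor was thus not the only difference. One that acts beside other changes would not show in this rho. As the scale between the lines is not fixed, it stays open as a source of the proximal rise. A peak list that favours low wild-type values, as the whole of the rise, is argued against by the proximal peaks above the proximal median of wild-type values. Their median log2 ratio was 0.38 (0.34 to 0.40, 12336 peaks). It was 0.84 over all proximal peaks and 0.18 among those above the median of the whole table, so a part that comes from the list stays open. Antibody signal from H3K4me2 or H3K4me3 cannot be told apart from methylation of promoters by other enzymes, since both could give the rho of 0.373 between the H3K4me1 change and wild-type H3K4me3. The genotype itself stays open, and with 1 value per line so does a difference between libraries.

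Another pattern was the higher share of regions with MED1, SNF2H and SRSF2 on chromosome 11. A higher share of H3K27ac-marked regions is argued against by the regions without listed H3K27ac, where the 3 shares were 22.0 points above the other autosomes on average (19.9 to 24.4, 1471 regions). A copy number above that of the reference library stays undecided: 39 of 39 pairs of a 10 Mb segment and a factor lay above the median of the other autosomes, but the 3 factors were picked for their excess there. The log2 shift needed to bring chromosome 11 to the share of the other autosomes was 0.38 for MED1, 0.47 for SNF2H and 0.30 for SRSF2. Against 3 copies in all cells of those libraries, these shifts lay below the 0.58 that 3 copies in place of 2 would give. For the other 14 factors the shift lay between 0.06 and 0.31. The estimate takes the same shift at every region of the chromosome, which was not tested. A copy number above the reference alone leaves unexplained the factors below every other autosome, such as BRG1 at regions with both marks (25.3% against 28.6%) and SUR2 at H3K4me3-only regions (30.9% against 33.3%). Whether some libraries had a copy number below their reference was not examined, so these factors decide nothing about copy number differences in general. No biological explanation was tested.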
